A study of Mus musculus with 36 samples.

How the data were processed

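The study measured RNA of the mouse colon and of colon tumours with a targeted sequencing panel for immune and cancer genes (QIAseq Targeted RNA, Mouse Immuno-Oncology panel, read on an Illumina MiSeq, per the labels' protocols). A panel of this kind amplifies 1 short stretch of each chosen transcript, so a value describes that stretch and not the whole gene. The deposited values are whole-number counts per gene, with no normalisation, in 1 table for the azoxymethane samples (25 libraries) and 1 for the MC-38 tumours (9 libraries). Each table has 993 entries. Of these, 988 are genes and 5 are control entries that the authors left at 0 in every library, and the control entries were left out of library sizes and tests. The submitters' processing notes name the mouse genome build mm9 and the tool DESeq2, with no version. The aligner, the counting program and whether molecular tags or reads were counted are not given in the sources used here, so every counting interval and every floor covers counting error only. Gene symbols were used as the authors gave them. The GRCm38 annotation at hand differs from that build, so it served for names only (974 of the 988 symbols were found in it) and no coordinates are given.

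Samples were grouped by the labels. The 36 samples fall into 9 groups, and 34 libraries were analysed: 1 MC-38 sample of each genotype (wild-type replicate 2 and sash replicate 3) was not analysed here. The labels do not state that each sample came from a separate mouse, so the p-values measure only the spread between these samples, which may be partly technical. No replicate pair agreed within sampling noise: the chi-square statistic per degree of freedom between replicates of a group was at least 6.17 and reached 205. No library was thus taken for a second deposit of another, and each was counted as 1 replicate, but amplified libraries of 1 sample can also differ by more than counting noise, so this does not show that the samples were independent.

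Counts were tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) after TMM scaling, with the filterByExpr filter at its minimum count of 10 and minimum total of 15, robust dispersion estimates and Benjamini-Hochberg adjustment within each comparison. A gene passed at an adjusted p below 0.05, and each adjusted p of a gene comes from this test. The sash and wild-type groups of the tumours, of the lesions and of the MC-38 tumours were each fitted on their own, the 3 groups of the cromolyn experiment together, and the 4 tumour and lesion groups together for the comparisons between stages and for the difference of genotype effects. Wild-type lesions were also compared with the AOM-only group, which had the same labelled treatment. Fold changes are log2 values with standard errors (SE), and the direction is that of the first group named minus the other. Levels are CPM (counts relative to the library total), scaled with TMM factors over all libraries of a table and given as mean ± SD.

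Fixed gene lists were tested with fry of limma 3.58.1, which asks whether the tested members of a list move, on balance, in 1 direction, and with camera with an estimated correlation between genes as an alternative. The 27 lists held 449 names, of which 241 were on the panel (2 through an older symbol). They covered mast cells, T cells, cytotoxic and NK cells, regulatory T cells, B and plasma cells, lymphoid tissue, macrophages and monocytes, neutrophils, neutrophil chemoattractants, dendritic cells, immune checkpoints, the interferon-gamma response, the type I interferon response, the Th17 and type 3 response, the Th2 and type 2 response, MHC class I, MHC class II, inflammatory cytokines, Toll-like receptors, stroma, smooth muscle, endothelium, epithelium, Wnt and growth signalling, proliferation, apoptosis and housekeeping. A list with fewer than 4 tested members was not tested. Each adjusted p of a list is from fry with Benjamini-Hochberg adjustment over the lists of a comparison, unless an estimated correlation is named.

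The genes named in the text followed a fixed rule. Kit came first, then up to 12 of the largest rises and 12 of the largest falls among the genes that passed (8 each for the comparisons between stages, between experiments and of genotype effects). Where fewer than 20 genes passed, all of them were named, together with those of smallest p up to 20, as values only. Up to 4 members of each described list, those of smallest p, were added. A gene with a mean under 10 counts in both groups appears only as a count. Some genes that the rule names are not reported here. Ratios of such genes are pooled counts over the groups' totals with exact 95% intervals. Against a group with 0 counts the bound comes from a floor of 3 counts over the whole group.

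The groups, the tests, the lists, the rule for named genes and most alternatives were fixed before the data were examined. These alternatives were DESeq2 1.42.0 with its own test, RLE size factors, library totals, scaling to the 2 housekeeping genes of the panel (Rpl13a and Tfrc), no filter on low counts, a fit over all 25 azoxymethane libraries, the replicate number as a block, camera, and leaving out each library in turn. Alternatives chosen after seeing the data were scaling to the 9 genes that the table lists after its control entries, a run term for the lesions, replicates 1 and 2 of the lesions alone, the AOM-only group as the control of the sash lesions, the tumours without wild-type replicates 2 and 4, Car4 as a covariate of the tumours and Col3a1 as a covariate of the MC-38 tumours. For the lists, camera and housekeeping scaling were fixed before, and their use with the other alternatives was chosen after seeing the data. The same holds for the block in the correlation of effects and for libraries left out of pooled counts.

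Replicate numbers recur between groups. In the lesions, same-numbered sash and wild-type libraries deviated from their group means together (correlations across genes of 0.38, 0.14 and 0.49, each the highest with its own number), so the numbers were taken to pair these samples. This pairing comes from the data and not from the labels. Column suffixes from the sequencer occur more than once among the 6 lesion libraries, so these came from more than 1 run, and a run term set replicate 3 of both genotypes against the others, since Rpl13a took 5.32% and 4.77% of the counts there and 8.23% to 11.4% in the others. The labels give no run or date, and the pairing was not told apart from a run shared by the replicate 3 libraries.

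The procedure was tested on simulated counts drawn from the real means and library sizes with 200 genes changed. For the tumours it recovered 65.7% of 2-fold and 96.0% of 4-fold changes, for the lesions 48.0% and 93.0%, for cromolyn with AOM 76.0% and 98.0%, for cromolyn after AOM 83.0% and 97.0%, and for the MC-38 tumours 82.0% and 94.9%. The difference of genotype effects recovered 14.0% and 60.0%. Fewer genes passed in these comparisons, and many changes ease the adjustment, so power may be overstated. A changed list of 10 genes was found in each simulation except that of the lesions (adjusted p = 0.110).

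At the lowest total, 449880 counts, 1 count equals about 2 CPM, so a gene of a few CPM rests on a handful of counts in each library.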

Results

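The panel was read in 9 groups of mouse samples. Tumours of the colon came from wild-type mice (n = 5) and from Kit W-sash mice (n = 5), called sash here, at an age of 32 weeks, 18 weeks after the last of 6 weekly injections of 10 mg/kg azoxymethane (AOM), a carcinogen of the colon epithelium. Sash mice carry a regulatory mutation at the Kit locus and are used as a mast cell-deficient strain. Colon samples with preneoplastic lesions came from both genotypes (n = 3 each) at 14 weeks, after 3 injections of AOM over 3 weeks and 3 further weeks. A separate set of wild-type mice of 14 weeks received AOM alone (n = 3), AOM together with cromolyn, a drug that stabilises mast cells (n = 3), or cromolyn for 3 weeks after AOM (n = 3). Tumours of MC-38, a colon carcinoma line of C57BL/6 mice, grown in wild-type (n = 4 analysed) and sash mice (n = 5 analysed) formed the last pair of groups. The series concerns the part that mast cells play in colon tumours, above all in their early steps.

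Total counts lay between 617698 and 1151533 in the wild-type tumours, 1051059 and 1264354 in the sash tumours, 616745 and 1149069 in the wild-type lesions, and 621846 and 816883 in the sash lesions. They lay between 470661 and 544886 for AOM only, 449880 and 497810 for cromolyn with AOM, and 479743 and 514208 for cromolyn after AOM. The MC-38 tumours had 633693 to 986415 counts in wild-type and 480136 to 889888 in sash mice. Of the 988 genes, 877 to 922 had at least 1 count in each AOM library and 815 to 863 in each MC-38 library. Rpl13a, a ribosomal protein gene, took 4.75% to 12.1% of the counts of an AOM library and 8.56% to 11.9% of an MC-38 library.

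Kit encodes the stem cell factor receptor on which mast cells depend, and it is also expressed outside mast cells. The sash mutation lies outside the coding sequence, so the Kit amplicon measures expression and not the mutation itself. Kit stood at 93.7, 323, 140, 451 and 123 CPM in wild-type tumours 1 to 5 and at 75.6, 49.4, 96.8, 80.5 and 69.0 CPM in sash tumours 1 to 5. It stood at 327, 510 and 455 CPM in wild-type lesions 1 to 3 and at 126, 112 and 143 CPM in sash lesions 1 to 3. For AOM only the values were 330, 354 and 422 CPM, for cromolyn with AOM 383, 605 and 308 CPM, and for cromolyn after AOM 671, 546 and 467 CPM. Kit was near the detection limit in the MC-38 tumours, with 8.09, 18.6, 8.39 and 6.01 CPM in wild-type replicates 1, 3, 4 and 5 and 2.02, 23.2, 13.2, 17.6 and 8.26 CPM in sash replicates 1, 2, 4, 5 and 6. In the lesions Kit fell by 1.78 on the log2 scale (SE 0.26, adjusted p = 0.0144), with 3 of 3 sash libraries below every wild-type library. In the tumours the difference was −1.65 (SE 0.45, adjusted p = 0.0779), with 4 of 5 sash libraries below every wild-type library.

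By pooled counts Kit was 2.90-fold lower in sash tumours (95% interval 2.60 to 3.25) and 3.36-fold in sash lesions (2.94 to 3.85). The first was 2.11 (1.86 to 2.39) without wild-type tumour 4. Cpa3, carboxypeptidase A3 of mast cell granules, had 15 counts in sash and 1574 in wild-type MC-38 tumours, a ratio of 109 (65.8 to 195). In the AOM tumours the counts were 21 and 191, a ratio of 11.6 (7.40 to 19.2), and 23.9 (11.9 to 56.1) without sash tumour 1, which held 13 of the 21. The lesions had 0 counts in sash and 31 in wild type. Cpa3 was thus at least 9.43-fold lower in sash from the floor of 3 counts (exact lower 95% limit 7.22). Wild-type lesion 3 held 24 of the 31 counts. The bound was 3.98-fold without it, and 6.01-fold and 6.02-fold without sash lesions 2 and 3. Tpsab1, the gene of a mast cell tryptase, had 3 against 529 counts in MC-38 tumours, a ratio of 183 (62.3 to 890), and was at least 145-fold lower without sash replicate 6, which held the 3. In AOM tumours it had 3 against 17 counts, of which wild-type tumour 1 held 13, and the ratio of 7.25 (2.10 to 38.6) was 2.29 (0.388 to 15.6) without that library. Without sash tumour 1, which held the 3, Tpsab1 was at least 5.67-fold lower in sash. Tpsb2, another tryptase, had 4 against 328 counts in MC-38 tumours (ratio 85.1, 32.9 to 314; at least 81.6-fold without sash replicate 5, which held the 4), 81 against 142 in AOM tumours (2.24, 1.70 to 2.99) and 12 against 33 in lesions (2.51, 1.26 to 5.33). The last ratio was 3.84 (1.49 to 12.6) without sash lesion 2 and 1.75 (0.861 to 3.83) without sash lesion 3. The tumour ratio was 1.55 (1.11 to 2.15) without wild-type tumour 1. In sash tumours 4 and 5 Tpsb2 stood at 29.9 and 23.3 CPM, within the wild-type range (13.6 to 55.8). Cpa3 stood at 9.63 CPM in sash tumour 1, against 10.8 and 11.9 CPM in wild-type tumours 4 and 3. These intervals cover counting error only. Kit in MC-38 tumours had 44 counts in sash and 31 in wild type (ratio 0.731, 0.446 to 1.18).

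**Figure D1:**
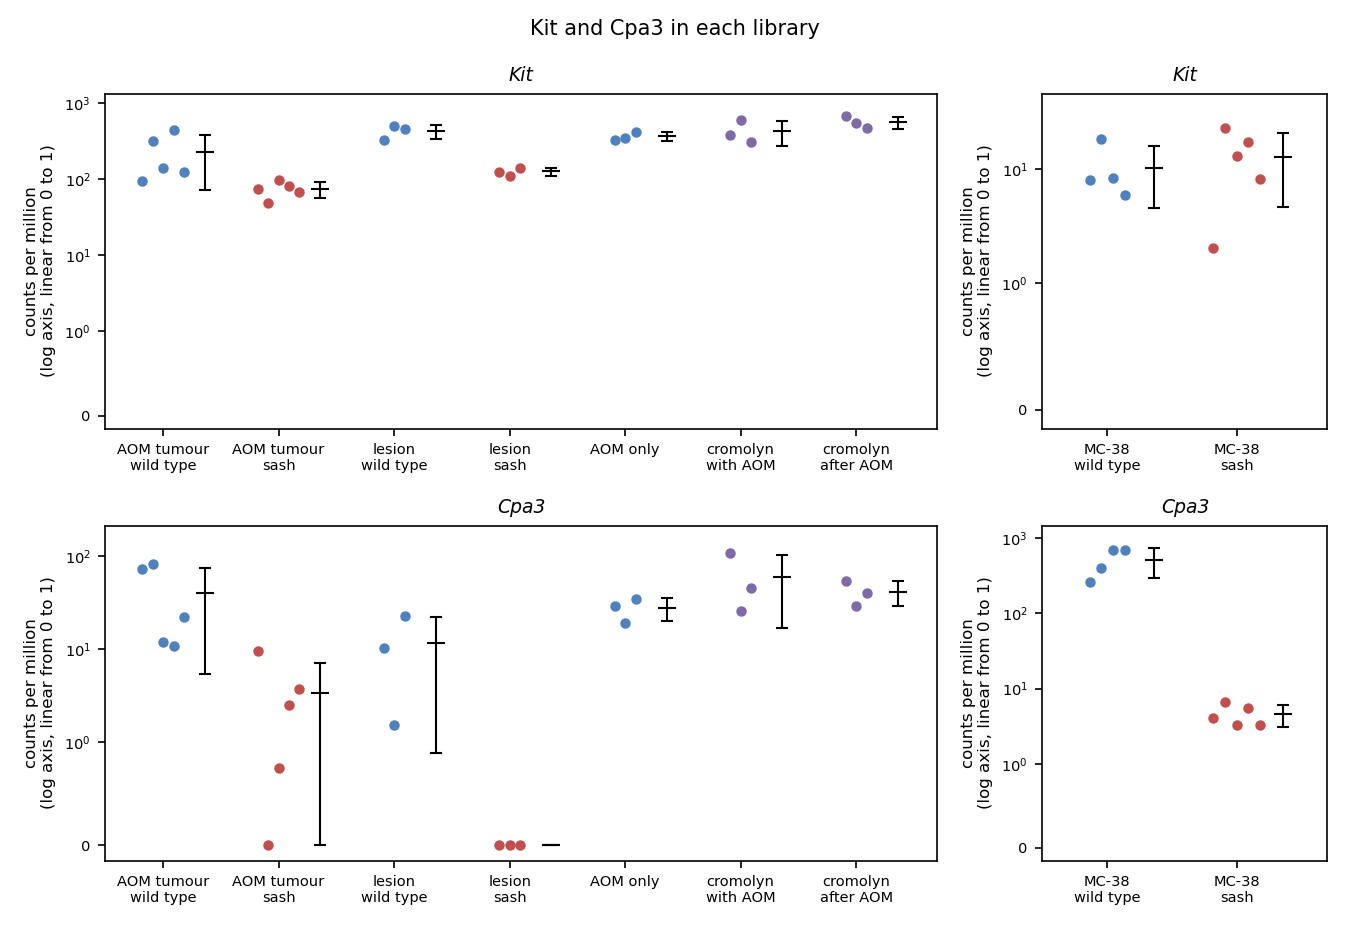
Kit and Cpa3 in CPM for each library of the AOM groups and the MC-38 groups, on an axis that is linear from 0 to 1 and logarithmic above. Points are libraries (red sash, blue wild type or AOM only, purple cromolyn), horizontal marks are group means and bars are SD, drawn down to 0 at most. Cpa3 lies between 259 and 699 in the wild-type and between 3.30 and 6.64 in the sash MC-38 tumours.

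The comparison of AOM tumours asked whether tumours of sash mice differ from those of wild-type mice in their immune transcripts. Sash tumours had the higher mean of several genes of neutrophils and of the chemokines that attract them, although no single gene passed. Cxcl2, a CXCR2 ligand that attracts neutrophils, stood at 2549 ± 1560 CPM (SD, n = 5) in sash and 329 ± 176 CPM (n = 5) in wild-type tumours (log2 difference 2.92, SE 0.59). Its receptor gene Cxcr2 stood at 265 ± 98.9 against 82.9 ± 32.6 CPM (1.65, SE 0.36), and Fpr1, a formyl peptide receptor of neutrophils, at 88.4 ± 23.0 against 19.6 ± 10.3 CPM (2.14, SE 0.49). Il1a, an interleukin 1 gene, stood at 505 ± 249 against 98.0 ± 62.2 CPM (2.33, SE 0.56). All 4 genes had the same adjusted p = 0.0684, the smallest of this comparison, and in each of them 5 of 5 sash libraries lay above every wild-type library.

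The same adjusted p belonged to 16 more genes. Higher in sash by mean were Nos2, the inducible nitric oxide synthase (1.74, SE 0.40), Hdc, which makes histamine (1.60, SE 0.33), Rgs16, a regulator of G protein signalling (1.56, SE 0.38), and the arginase gene Arg2 (1.40, SE 0.32). The same held for Selp, the P-selectin of activated endothelium and platelets (1.26, SE 0.30), Shmt2, a mitochondrial enzyme of serine metabolism (0.99, SE 0.18), and Nfkbia, an inhibitor and target of NF-kappaB (0.98, SE 0.20). It also held for the chromatin helicase gene Hells (0.89, SE 0.19), the endotoxin co-receptor gene Cd14 (0.89, SE 0.20), the TNF receptor gene Tnfrsf1b (0.73, SE 0.16) and Sgms1, a sphingomyelin synthase (0.48, SE 0.12). By mean the lower genes were Fgf18, a fibroblast growth factor (−1.59, SE 0.38), the phosphatase gene Inpp4b (−1.01, SE 0.24), the receptor tyrosine kinase gene Erbb2 (−0.91, SE 0.21), the glypican gene Gpc4 (−0.69, SE 0.12) and Foxn3, a forkhead factor (−0.65, SE 0.16). For Nos2, Selp, Hells, Cd14 and Inpp4b 4 of 5 sash libraries lay beyond every wild-type library, and for the other 11 genes 5 of 5 did. Hdc is expressed by neutrophils and other myeloid cells as well as by mast cells, and it stood at 184 ± 74.0 CPM in sash against 59.5 ± 21.8 CPM in wild type, opposite to Cpa3 (−3.57, SE 0.90, adjusted p = 0.0740).

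As groups, 3 of the 20 lists tested, which can share genes, moved upwards in sash tumours. The neutrophil list (5 of 5 members above 0, median log2 difference 0.89), the neutrophil chemoattractant list (8 of 8 above 0, median 2.29) and the inflammatory cytokine list (8 of 12 above 0, median 1.05) each had adjusted p = 0.0481, and adjusted p = 0.365 with an estimated correlation. No member passed over all genes tested. Adjusted over the list alone, 2 neutrophil genes and 8 chemoattractant genes were higher, and among the cytokines 7 were higher and 1 lower. Beyond Cxcl2, the chemoattractant list held Cxcl1 at 2046 ± 999 against 375 ± 210 CPM (2.41, SE 0.61) and Cxcl3 at 783 ± 225 against 168 ± 101 CPM (2.18, SE 0.58). Il1b stood at 2632 ± 1474 against 591 ± 368 CPM and Il6 at 343 ± 237 against 49.2 ± 53.8 CPM. The mast cell list had 6 of 7 members below 0 (median −0.95, adjusted p = 0.147), and 1 member was higher and 2 were lower adjusted over the list alone.

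No other list passed in the tumours. The adjusted p was 0.661 for T cells (median −0.07, against an upward test), 0.358 for cytotoxic and NK cells (−0.81), 0.388 for regulatory T cells (0.21), 0.863 for lymphoid tissue (−0.06), 0.383 for macrophages and monocytes (0.29), 0.716 for dendritic cells (0.27) and 0.545 for immune checkpoints (0.14). It was 0.833 for the interferon-gamma response (−0.20), 0.516 for the type I interferon response (−0.27), 0.105 for the Th17 and type 3 response (0.14), 0.456 for MHC class I (−0.31) and 0.516 for MHC class II (0.30). For the Toll-like receptors it was 0.768 (−0.20, against an upward test), for stroma 0.516 (−0.27), for endothelium 0.236 (0.28) and for apoptosis 0.890 (−0.01, against an upward test). The B and plasma cell list (2 tested members), the Th2 list (3), the epithelium list (3), the Wnt and growth list (3), the proliferation list (2) and the housekeeping list (2) were too short for a test here, and the panel held 0 genes of the smooth muscle list. In no comparison did the last 5 of these reach 4 tested members.

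Over the 797 genes tested in the tumours, edgeR called 0 genes, 159 had an unadjusted p below 0.05 (76 higher, 83 lower) where 39.85 would be expected by chance, and DESeq2 called 82 (40 higher, 42 lower). A fit of all 25 AOM libraries called 88 (41 higher, 47 lower), and library totals 2. Wild-type replicate 4 lay apart from the others, with a mean log2 level of 4.45 over the chemoattractant list against 7.38 to 7.92, and with Car4, a gene of the surface mucosa, at 14143 CPM against 226 to 3904 CPM in the other wild-type tumours. Without it 7 genes passed, without wild-type replicate 2 there was 1, and without sash replicate 1 there were 17. Wild-type replicate 2 had the B cell gene Ms4a1 at 241 CPM against 3.92 to 7.55 CPM in the other wild-type tumours, and without both of these libraries 6 genes passed (5 higher, 1 lower). The list calls were lost on leaving out any of 8 libraries, with adjusted p between 0.0610 and 0.120. Without sash replicate 1 the neutrophil list was lost (0.0518), while without wild-type replicate 4 the cytokine list was lost (0.0902). Scaling to the housekeeping genes shifted the median of all genes by 0.12 and gave adjusted p = 0.0651 for the neutrophil and chemoattractant lists and 0.137 for the cytokine list. The calls of all 3 lists also ended with reference gene scaling (0.1003), with RLE size factors (0.0502), with library totals (0.0511) and without a low-count filter (0.0551). With Car4 as a covariate the neutrophil and chemoattractant calls ended (0.114) and the cytokine list had 0.0442. Without wild-type replicates 2 and 4 the cytokine call ended (0.127), while the other lists had 0.0361. Over the settings of this test the adjusted p of these lists ran from 0.000780 to 0.154.

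**Figure D2:**
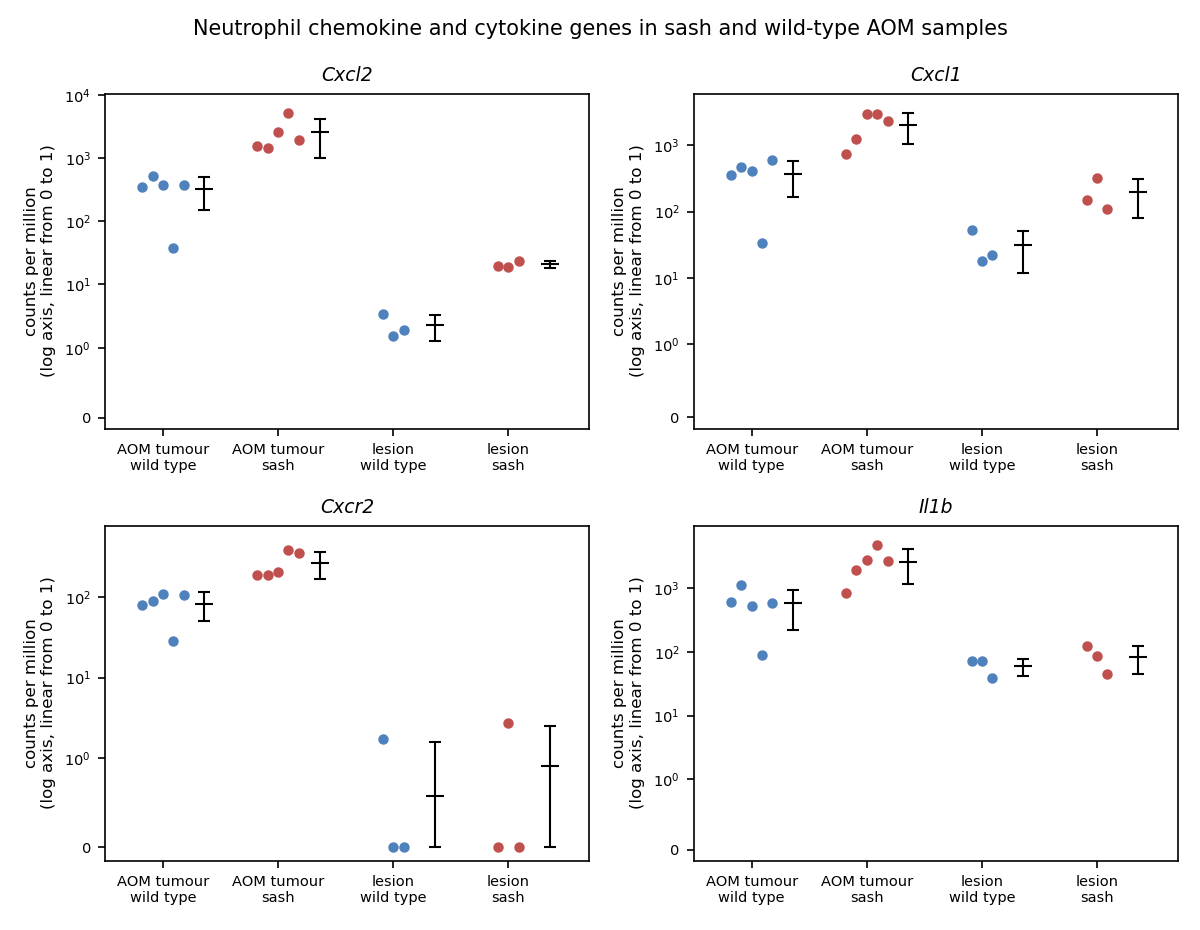
Cxcl2, Cxcl1, Cxcr2 and Il1b in CPM for each library of the wild-type and sash AOM tumours and preneoplastic lesions, on an axis that is linear near 0 and logarithmic above. Points are libraries (red sash, blue wild type), horizontal marks are group means and bars are SD, drawn down to 0 at most. The mean of Cxcl2 is 2549 in sash and 329 in wild-type tumours, and 20.8 in sash and 2.29 in wild-type lesions.

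The comparison of preneoplastic lesions put the same question to an early stage. Of the lists tested, the type I interferon response moved downwards in sash lesions and neutrophil chemoattractants upwards (adjusted p = 0.0396 each, and adjusted p = 0.159 with an estimated correlation). Oas3 and Oas2, antiviral synthetases induced by interferon, stood at 129 ± 41.6 and 109 ± 48.3 CPM in sash (n = 3) against 991 ± 322 and 1069 ± 589 CPM in wild type (n = 3), and fell by 2.99 (SE 0.34, adjusted p = 0.0102) and 3.36 (SE 0.56, adjusted p = 0.0159) on the log2 scale. Irf7, the master regulator of the interferon response, fell by 1.89 (SE 0.25, adjusted p = 0.0144), from 4012 ± 1086 to 1108 ± 100 CPM. Cxcl2 rose from a mean of 2.29 to 20.8 CPM (3.14, SE 0.52, adjusted p = 0.0157) and Cxcl5, another CXCR2 ligand, from 42.9 ± 21.0 to 267 ± 135 CPM (2.60, SE 0.52, adjusted p = 0.0401). In each of these genes 3 of 3 sash libraries lay beyond every wild-type library.

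Other genes that rose were Edn1, which encodes endothelin 1 (1.30, SE 0.27), and Nfkbia (0.85, SE 0.18), both with adjusted p = 0.0476. Among the falls were single B cell surface genes, although the B and plasma cell list did not pass (adjusted p = 0.0725). Ms4a1 (CD20) stood at 38.6 ± 35.9 against 573 ± 437 CPM (−4.02, SE 0.77, adjusted p = 0.0326) and Cd22 at 24.6 ± 16.2 against 191 ± 132 CPM (−3.04, SE 0.65, adjusted p = 0.0476). Cxcl13, which draws B cells into follicles, fell by 2.45 (SE 0.38, adjusted p = 0.0144), and H2-Eb2, a class II gene, by 3.19 (SE 0.48, adjusted p = 0.0144). Further falls were Tmigd1, an epithelial adhesion gene (−3.07, SE 0.50, adjusted p = 0.0157), the epithelial membrane gene Emp1 (−2.74, SE 0.58, adjusted p = 0.0476) and the class I-like gene H2-T24 (−2.68, SE 0.50, adjusted p = 0.0317). Reads of H2 genes can be shared between near-identical members of the family, so single H2 values are uncertain. B2m, the light chain of class I molecules, fell by 0.91 (SE 0.18, adjusted p = 0.0401).

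Of the 20 lists tested in the lesions, 4 passed, each with adjusted p = 0.0396. The type I interferon list (9 of 10 members below 0, median −1.48) moved downwards as above. Over all genes 5 members fell, and 8 adjusted over the list alone. Beside the genes above these included Bst2, the tetherin gene (−1.67, SE 0.25, adjusted p = 0.0144). The mast cell list (4 of 5 below 0, median −0.37) also moved downwards, with adjusted p = 0.584 with an estimated correlation. Kit was its only member that fell, over all genes and adjusted over the list alone, and Cma1 (−0.37, SE 0.85) and Hpgds (0.13, SE 0.32) lay within their error. Upwards moved the chemoattractant list (4 of 4 above 0, median 2.61, 2 higher and 3 adjusted over the list alone) and the inflammatory cytokine list (8 of 9 above 0, median 0.44, 1 higher and 2 adjusted over the list alone), both with adjusted p = 0.159 with an estimated correlation. With the replicate number as a block all 4 calls were lost, at adjusted p = 0.0753 for the interferon and cytokine lists, 0.106 for the chemoattractants and 0.214 for mast cells. With RLE size factors all 4 calls ended as well (0.0502), as they did without a low-count filter (0.0565 to 0.113). Housekeeping scaling ended the interferon (0.108), cytokine (0.743) and mast cell calls and not that of the chemoattractants (0.0287). Reference gene scaling ended the chemoattractant and mast cell calls (0.0593) and the cytokine call (0.156), and the interferon list had 0.0353. A fit of all 25 libraries ended the mast cell (0.0604) and chemoattractant (0.127) calls and not those of interferon and cytokines (0.0369). Over all settings the adjusted p of these lists ran from 0.000906, for mast cells against the AOM-only group, to 0.939, for mast cells with housekeeping scaling.

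The B and plasma cell list had 9 of 10 members below 0 (median −2.97, adjusted p = 0.0725), with 3 lower over all genes and 8 adjusted over the list alone, and it passed with housekeeping scaling (0.0171) but in no other setting (0.0547 to 0.342). The wild-type lesions also stood above the AOM-only group in this list (8 of 10 above 0, median 1.86, adjusted p = 0.211), with 5 members higher over all genes and 7 adjusted over the list alone. Ms4a1 was 84.4 ± 41.0 CPM in that group (2.79, SE 0.56, adjusted p = 0.0154), and the list in sash lesions had a median of −1.30 against it (adjusted p = 0.170). In the lymphoid tissue list 6 of 6 members lay below 0 (−1.76, adjusted p = 0.194), and 6 of 6 lay above 0 in wild-type lesions against AOM only (1.79, adjusted p = 0.291; 2 higher over all genes and 4 adjusted over the list alone). In the T cell list 13 of 14 lay below 0 (−0.72, adjusted p = 0.343). The interferon-gamma list had 8 of 10 members above 0 (0.56, adjusted p = 0.246), opposite in sign to the type I list, and MHC class II had 6 of 7 above 0 (0.82, adjusted p = 0.246; 4 higher and 1 lower adjusted over the list alone). Among checkpoint genes, Lgals9, the galectin 9 gene, fell by 1.39 (SE 0.22, adjusted p = 0.0144), while Ido1, a tryptophan-degrading enzyme, stood at 78.1 ± 29.1 against 22.8 ± 8.77 CPM (1.75, SE 0.45, adjusted p = 0.0790). All other lists had an adjusted p of at least 0.218, and in the macrophage, checkpoint, Th17 and stroma lists the median lay above 0 while the test pointed downwards.

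In the lesions 22 of 775 genes passed (4 higher, 18 lower), against 84 with the replicate number as a block (25 higher, 59 lower), which included all 22. Scaling to the 9 listed reference genes shifted the median of all genes by −0.24 and called 41 genes (2 higher, 39 lower). Without sash replicate 2 no gene passed in edgeR, without sash replicate 3 there were 13, and without wild-type replicate 3 there were 68. Without a low-count filter 36 passed, and 190 against AOM only. DESeq2 called 70 genes and 148 had an unadjusted p below 0.05 in edgeR. Leaving out any single library ended all 4 list calls, except that without wild-type replicate 3 the mast cell list (0.0389) and the interferon list (0.0211) were kept. Within replicates 1 and 2, inferred to be 1 run, 16 genes passed and the interferon list had adjusted p = 0.0971, and with run as a term 66 genes passed, all 22 among them.

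**Figure D3:**
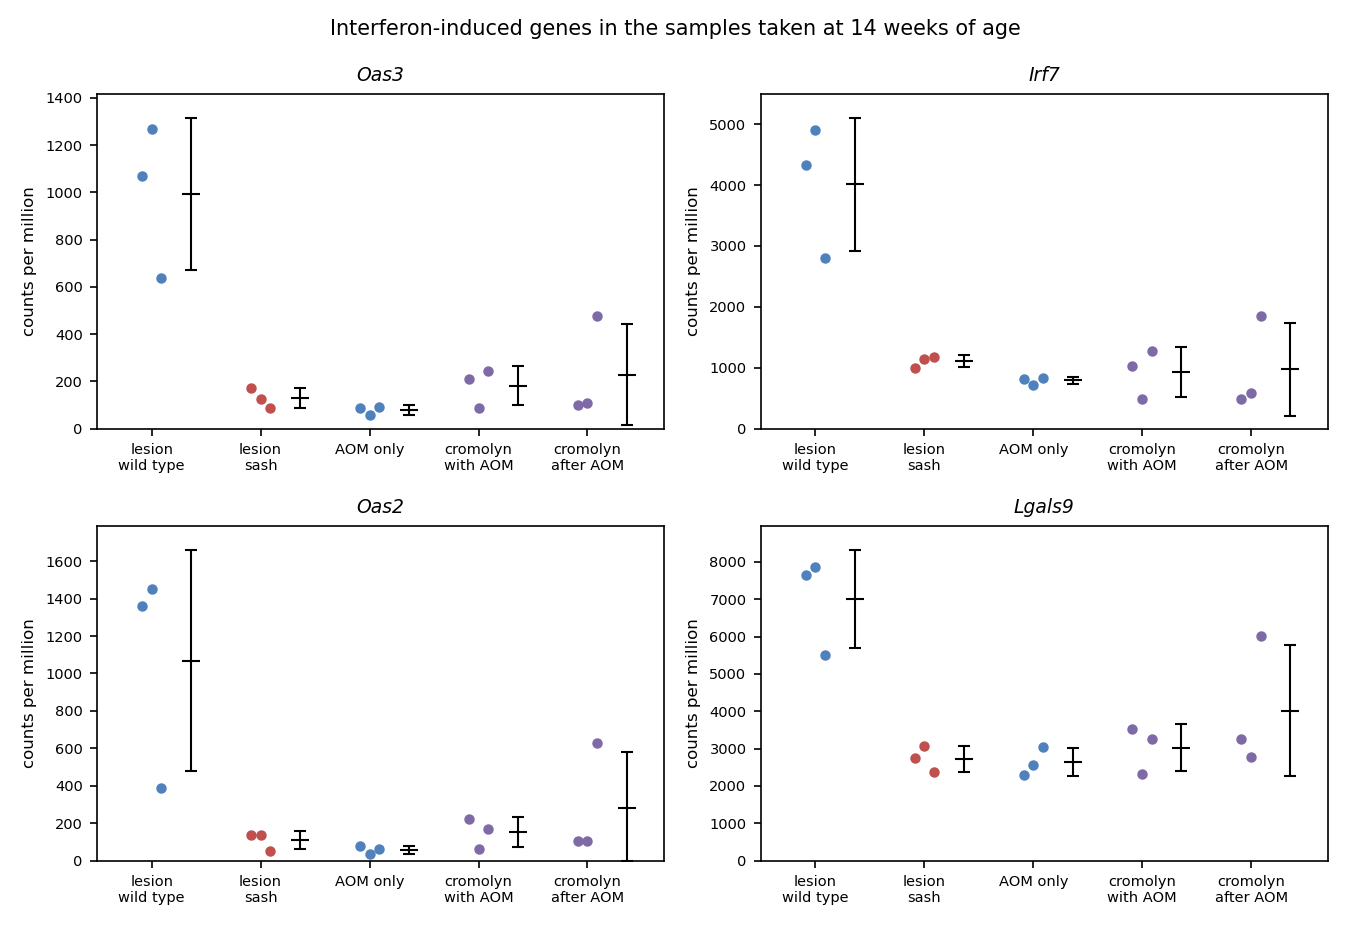
Oas3, Irf7, Oas2 and Lgals9 in CPM for each library of the 5 groups of 14-week samples, on linear axes. Points are libraries (red sash lesions, blue wild-type lesions and AOM only, purple cromolyn), horizontal marks are group means and bars are SD, drawn down to 0 at most. The mean of Oas3 is 991 in the wild-type lesions, 129 in the sash lesions and 78.6 in the AOM-only group.

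Wild-type lesions and the AOM-only group carry the same labelled genotype, age and AOM treatment, and their comparison shows how far the experiments differ. The interferon genes that fell in sash lesions were higher in wild-type lesions than in this other wild-type group: Oas2 rose by 4.24 (SE 0.54, adjusted p = 0.00208), Oas3 by 3.66 (SE 0.32, adjusted p = 0.000430), and Irf7 by 2.34 (SE 0.24, adjusted p = 0.000492), from 791 ± 60.2 CPM (n = 3) to 4012 ± 1086 CPM (n = 3). Also higher were Tnfrsf18, the GITR gene (4.30, SE 0.46), the interferon regulatory factor gene Irf5 (3.95, SE 0.43), and the epithelial adhesion gene Ceacam12 (3.55, SE 0.64). Others were Emp1 (3.34, SE 0.57), the T cell adaptor gene Trat1 (3.30, SE 0.66) and Pax5, a B cell transcription factor (3.12, SE 0.71). Lower were Fpr2, a formyl peptide receptor (−2.02, SE 0.45), the matrix gene Spon2 (−1.96, SE 0.33), Cd248, an antigen of pericytes and fibroblasts (−1.83, SE 0.52), and the collagen gene Col3a1 (−1.80, SE 0.39). So were the endothelin receptor gene Ednrb (−1.75, SE 0.36), Col8a2, another collagen (−1.64, SE 0.44), and Ggt1, a glutamyl transferase (−1.60, SE 0.47). The adjusted p of these genes lay between 0.000520 and 0.0471, in each 3 of 3 libraries lay beyond every AOM-only library, and Kit differed by 0.21 (SE 0.21, adjusted p = 0.505).

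Between these experiments 119 of 762 genes passed (66 higher, 53 lower), against 25 higher and 60 lower with housekeeping scaling, which shifted the median of all genes by −0.44. The type I interferon list moved upwards (8 of 10 higher over all genes and adjusted over the list alone, median 1.18, adjusted p = 0.0373, and adjusted p = 0.657 with an estimated correlation). The endothelium list moved downwards (2 of 7 lower, 3 adjusted over the list alone, median −0.32, adjusted p = 0.0373, and adjusted p = 0.777 with an estimated correlation), its lower members being Vegfc, a growth factor of lymphatic vessels (−1.14, SE 0.27), and the VEGF receptor gene Kdr (−0.98, SE 0.29). Both calls were lost on leaving out any library, at 0.0605 to 0.191, except that without wild-type lesion 3 the interferon list kept 0.0227. With RLE size factors both calls ended too (0.0665 for interferon and 0.0789 for endothelium), as with reference gene scaling (0.0582 and 0.137). The endothelium call also ended with housekeeping scaling (0.283), without a low-count filter (0.119) and in the fit of all 25 libraries (0.329), where the interferon list had 0.0321, 0.0312 and 0.0113. The number of genes was 64 without wild-type lesion 1, 57 without lesion 2, 268 without lesion 3, and 11, 25 and 34 without AOM-only replicates 1, 2 and 3. Against the AOM-only group the sash lesions had a median interferon list difference of 0.24, with Oas3 at 0.68 and Irf7 at 0.47, opposite in sign to the difference from their own wild-type controls. In the cytotoxic, checkpoint and inflammatory cytokine lists of this comparison the median and the test differed in sign.

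Cromolyn given with AOM was compared with AOM only, to ask what blocking mast cells during exposure to the carcinogen does. Of single genes 1 rose and 1 fell. Psmb9, a subunit of the immunoproteasome, rose from 1435 ± 252 CPM (n = 3) to 2926 ± 375 CPM (n = 3; 1.03, SE 0.16, adjusted p = 0.0219), and Abcg2, an efflux transporter of the epithelium, fell from 1511 ± 135 to 779 ± 105 CPM (−0.95, SE 0.16, adjusted p = 0.0245). Ciita, the regulator of class II genes, stood at 313 ± 69.8 against 154 ± 21.0 CPM (1.02, SE 0.23) and the invariant chain gene Cd74 at 17783 ± 1903 against 10963 ± 912 CPM (0.70, SE 0.16), both with adjusted p = 0.0651. Gzma, a granzyme of cytotoxic cells, stood at 182 ± 46.9 against 63.0 ± 6.62 CPM (1.53, SE 0.40, adjusted p = 0.0800).

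Other genes near the threshold had an adjusted p between 0.0563 and 0.0747. Higher by mean were the lymphoid chemokine gene Ccl19 (3.44, SE 0.80), Ceacam12 (1.89, SE 0.38), the ubiquitin-like gene Ubd (1.58, SE 0.34), and the T cell kinase gene Zap70 (1.10, SE 0.27). So were the T cell chemokine gene Ccl5 (1.02, SE 0.25), the nucleic acid sensor gene Zbp1 (0.95, SE 0.21), Nkg7, a granule gene of cytotoxic cells (0.86, SE 0.18), and the peptide transporter gene Tap1 (0.85, SE 0.21). The class II genes H2-Ab1 (0.69, SE 0.18), H2-Aa (0.58, SE 0.15) and H2-Eb1 (0.58, SE 0.14) were higher too, as was the proliferation gene Mki67 (0.66, SE 0.16). Lower were the phosphatase gene Cdc14a (−0.63, SE 0.13), Casp1, the inflammasome caspase (−0.48, SE 0.11), and the ubiquitin ligase adaptor Ndfip1 (−0.47, SE 0.12). In all of these genes 3 of 3 libraries lay beyond every AOM-only library. Kit differed by 0.23 (SE 0.23, adjusted p = 0.601), and Il13, a type 2 cytokine, had 31 counts against 3 (ratio 11.1, 95% interval 3.45 to 56.5). Cromolyn replicate 1 held 22 of the 31, and the ratio was 4.71 (1.18 to 27.1) without it and 21.2 (3.54 to 865) without AOM-only replicate 2.

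MHC class I (8 of 8 members above 0, median 0.43) and MHC class II (6 of 6 above 0, median 0.70) moved upwards among 19 lists. Each had adjusted p = 0.0378, or 0.216 with an estimated correlation. Over all genes 1 class I member and 0 class II members were higher, and adjusted over the list alone 4 and 6. Housekeeping scaling, which shifted the median of all genes by −0.26, ended both list calls (0.521), as did reference gene scaling (0.121) and the fit of all 25 libraries (0.390 for class I and 0.503 for class II). Over all settings of this test the adjusted p ran from 0.00313 to 0.521. The T cell list had 14 of 14 members above 0 (0.55, adjusted p = 0.313), the type I interferon list 10 of 10 (0.27, adjusted p = 0.392), the lymphoid tissue list 7 of 7 (1.44, adjusted p = 0.312), cytotoxic and NK cells 7 of 9 (0.75, adjusted p = 0.196) and B and plasma cells 8 of 10 (1.59, adjusted p = 0.313). The B cell gene Ms4a1 stood at 918, 130 and 249 CPM in the libraries with cromolyn and at 130, 49.7 and 73.7 CPM in those without. The mast cell list had adjusted p = 0.680, and in the inflammatory cytokine list a median of 0.02 stood against a downward test (adjusted p = 0.902).

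Only 2 of 768 genes passed (1 higher, 1 lower), with 17 higher and 1 lower by library totals, 0 higher and 1 lower with housekeeping scaling, and 1 higher and 2 lower with reference gene scaling, while DESeq2 called 39 and 127 had an unadjusted p below 0.05. In the fit of all 25 AOM libraries edgeR called 0, and 43 had an unadjusted p below 0.05. The count was 0 without cromolyn replicate 1 or without AOM-only replicate 2 or 3, 15 without cromolyn replicate 2, 3 without cromolyn replicate 3 and 5 without AOM-only replicate 1. Both list calls were lost without any 1 library (0.0926 to 0.159), except cromolyn replicate 2 (0.0223).

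Cromolyn given after AOM was compared with the same controls, to ask about the time after exposure. Single genes rose and fell, and no list passed. Trat1, a T cell adaptor gene, rose from 34.5 ± 26.8 CPM (n = 3) to 440 ± 138 CPM (n = 3; 3.70, SE 0.76, adjusted p = 0.0356), Ccl19 from 3.50 ± 2.31 to 44.6 ± 31.5 CPM (3.57, SE 0.79, adjusted p = 0.0339) and Madcam1, the gut homing addressin, from 101 ± 24.4 to 276 ± 119 CPM (1.44, SE 0.34, adjusted p = 0.0356). Il13 rose from 3 to 40 counts, a ratio of 13.4 (95% interval 4.26 to 67.6; adjusted p = 0.0427), and of 25.7 (4.35 to 1039) without AOM-only replicate 2. Cd34, a gene of vessels and stromal progenitors, fell from a mean of 776 to 426 CPM (−0.87, SE 0.18, adjusted p = 0.0333), and Cd248 from 99.3 ± 14.4 to 32.7 ± 8.64 CPM (−1.60, SE 0.35, adjusted p = 0.0339).

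The smallest adjusted p was that of Ceacam12, which rose from a mean of 17.8 to 145 CPM (3.05, SE 0.37, adjusted p = 0.00142). Further rises were Nos2 (2.18, SE 0.48), the CD30 gene Tnfrsf8 (1.60, SE 0.40), Socs1, a brake on cytokine signals (1.53, SE 0.37), and the orphan nuclear receptor gene Nr4a2 (1.51, SE 0.29). Zbp1 (1.18, SE 0.21), Mlph, a gene of vesicle transport (1.11, SE 0.24), and Emp1 (1.07, SE 0.20) also rose, as did both proliferation genes tested, Birc5 (0.75, SE 0.17) and Mki67 (0.68, SE 0.16). Further falls were the fatty acid receptor gene Cd36 (−1.34, SE 0.30), Lrrc32, which tethers latent TGF-beta (−1.25, SE 0.32), the cytokine gene Il15 (−1.23, SE 0.31), and the aminopeptidase gene Anpep (−0.93, SE 0.24). The secreted protein genes Crispld2 (−0.91, SE 0.21) and Spon2 (−0.84, SE 0.20) fell, as did Vegfc (−0.79, SE 0.18) and Abcg2 (−0.78, SE 0.16). The last falls named were the cathepsin gene Ctss (−0.75, SE 0.19), Igfbp5, which binds insulin-like growth factors (−0.74, SE 0.15), and Casp1 (−0.53, SE 0.11). The adjusted p of these genes lay between 0.0257 and 0.0466, and in every gene named here 3 of 3 libraries lay beyond each AOM-only library. Kit differed by 0.60 (SE 0.23, adjusted p = 0.153).

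No list of 19 passed after AOM, the smallest adjusted p being 0.368. It belonged among others to B and plasma cells (9 of 10 members above 0, median 1.53, 0 higher), lymphoid tissue (7 of 7 above 0, 1.25, 1 higher and 2 adjusted over the list alone), stroma (5 of 7 below 0, −0.48, 2 lower adjusted over the list alone) and endothelium (4 of 7 below 0, −0.07, 1 lower). The mast cell list had 3 of 5 above 0 (0.03, adjusted p = 0.769). In the inflammatory cytokine list Nos2 rose and Casp1 and Il15 fell (median −0.08, adjusted p = 0.615).

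After AOM 37 of 768 genes passed (18 higher, 19 lower), against 20 higher and 8 lower by library totals, 8 higher and 22 lower with reference gene scaling, and 6 higher and 0 lower with housekeeping scaling, which shifted the median of all genes by 0.12 (library totals by 0.11). In the fit of all 25 AOM libraries edgeR called 0, and 69 had an unadjusted p below 0.05, against 168 here and 50 called by DESeq2. Leaving out cromolyn replicate 1, 2 or 3 gave 6, 8 or 2 genes, and leaving out AOM-only replicate 1, 2 or 3 gave 2, 1 or 2.

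The schedules of cromolyn were compared directly, since a gene that passed for 1 schedule alone is not thereby shown to differ between them. Emp1 had the smallest adjusted p, at 779 ± 156 CPM (n = 3) with AOM and 1744 ± 349 CPM (n = 3) after it (−1.15, SE 0.20, adjusted p = 0.0629). Nkg7 stood at 319 ± 25.5 against 174 ± 22.6 CPM (0.88, SE 0.18), Me1, malic enzyme, at 363 ± 22.7 against 762 ± 105 CPM (−1.05, SE 0.22) and Tmigd1 at 398 ± 42.4 against 746 ± 58.8 CPM (−0.90, SE 0.18), with adjusted p = 0.0697 each. By edgeR 0 of 768 genes passed and 64 had an unadjusted p below 0.05, and DESeq2 called 6 (3 higher, 3 lower). With housekeeping scaling, which shifted the median of all genes by −0.38, 0 were higher and 4 lower, and by library totals 0 and 3. Without cromolyn replicate 1 of either schedule 1 gene passed.

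In the same comparison Ccl5 (0.99, SE 0.25) and Spon2 (0.83, SE 0.20) had adjusted p = 0.199, Lpcat4, a lipid acyltransferase, −0.78 (SE 0.20, adjusted p = 0.251), and Ceacam12 −1.15 (SE 0.31, adjusted p = 0.277). The class II genes H2-Ab1 (0.58, SE 0.18) and H2-Aa (0.49, SE 0.15) had adjusted p = 0.331, and Psmb9 (0.51, SE 0.16) 0.338. The cytotoxic, MHC class I and MHC class II lists had the smallest adjusted p of 19 lists, 0.379, with medians of 0.50, 0.30 and 0.48. The type I interferon list had a median of −0.05 against an upward test (adjusted p = 0.991), and the B cell and Toll-like receptor lists also differed in sign between median and test.

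The effects of the sash mutation in lesions and of cromolyn were compared across 755 genes, as these experiments share no library. Across genes, which are not independent replicates, the log2 effects of sash and of cromolyn with AOM had a Pearson r of −0.47 and a Spearman rho of −0.32, and those of sash and of cromolyn after AOM −0.50 and −0.34. Of 100 splits of both experiments, 14 gave a correlation as large with AOM and 20 after it. Emp1 fell in sash lesions against wild-type lesions, not against AOM only (0.61), and rose with cromolyn after AOM. These controls differed in 119 genes.

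MC-38 tumours addressed the role of host mast cells in an established tumour line. The 3 mast cell proteases fell in sash hosts. The MHC class II list moved upwards (adjusted p = 0.0391, or 0.588 with an estimated correlation). Its 3 members that rose did not pass with housekeeping or reference gene scaling. Cpa3 fell from 509 ± 218 CPM (n = 4) to 4.56 ± 1.47 CPM (n = 5; −6.72, SE 0.38, adjusted p = 8.12e-07), Tpsb2 from 107 ± 52.7 to 0.879 ± 1.97 CPM (adjusted p = 0.000293) and Tpsab1, with 3 counts in sash, by the ratio given above (adjusted p = 0.000293). H2-Eb1 and H2-Ab1, chains of class II molecules, rose from 3483 ± 721 to 6350 ± 1043 CPM (0.87, SE 0.17, adjusted p = 0.0422) and from 38804 ± 5490 to 61522 ± 8054 CPM (0.67, SE 0.14, adjusted p = 0.0466), and Ciita rose from 123 ± 15.7 to 220 ± 39.7 CPM (0.84, SE 0.17, adjusted p = 0.0422).

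The remaining genes that passed were Thbs4, a thrombospondin of the matrix (2.75, SE 0.56, adjusted p = 0.0440), the adaptor gene Sla (0.86, SE 0.15, adjusted p = 0.0221), and Rbm3, an RNA-binding protein induced by cold (−0.84, SE 0.18, adjusted p = 0.0466). In all 9 genes 5 of 5 sash libraries lay beyond every wild-type library. Below the threshold, with adjusted p = 0.0508, were Cd163, a scavenger receptor of macrophages (49.8 ± 42.9 against 5.36 ± 2.92 CPM, 3.13, SE 0.71), the macrophage lectin gene Clec10a (1.98, SE 0.45), Leprot (0.84, SE 0.19), Casp1 (−0.76, SE 0.17) and Numa1, a gene of the mitotic spindle (0.60, SE 0.14). The adhesion gene Cadm1 (−0.84, SE 0.20), the proteasome gene Psma2 (−0.80, SE 0.20), the eosinophil granule gene Prg2 (4.18, SE 0.98; 122 ± 113 against 6.55 ± 5.59 CPM), the interferon-induced gene Ifitm3 (−0.66, SE 0.17) and the acetyltransferase gene Kat6a (0.57, SE 0.15) had adjusted p values from 0.0667 to 0.0815, with 4 of 5 sash libraries beyond every wild-type library for Cadm1 and Prg2. Kit was too low for the test.

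**Figure D4:**
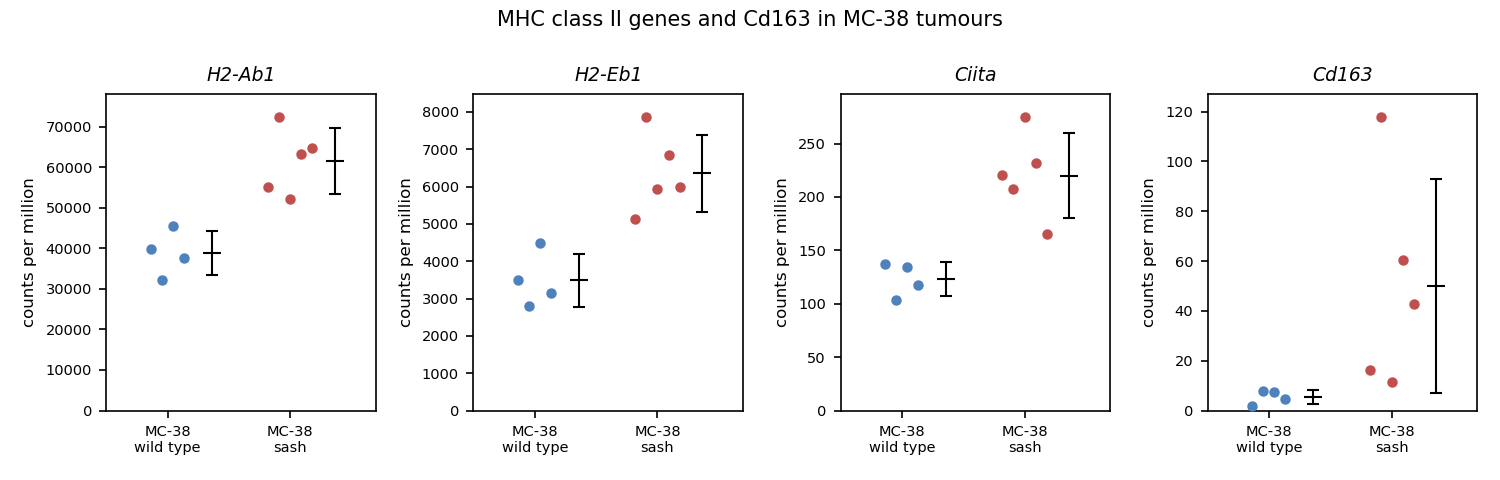
H2-Ab1, H2-Eb1, Ciita and Cd163 in CPM for each MC-38 library, on linear axes. Points are libraries (red sash, blue wild type), horizontal marks are group means and bars are SD, drawn down to 0 at most. The mean of H2-Ab1 is 61522 in sash and 38804 in wild-type hosts.

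Of 21 lists tested in the MC-38 tumours, mast cells moved downwards (5 of 5 members below 0, median −6.27, 3 lower over all genes and adjusted over the list alone; adjusted p = 0.000279, and adjusted p = 0.00204 with an estimated correlation). Its median was −3.33, −3.19 and −3.10 without wild-type replicates 1, 4 and 5 and −2.34 without a low-count filter. MHC class II moved upwards as above (4 of 5 above 0, median 0.67, 3 higher over all genes and adjusted over the list alone). The Th2 and type 2 list had 5 of 5 members above 0 (1.14, adjusted p = 0.365), with the eosinophil receptor gene Ccr3 at a mean of 71.1 against 17.5 CPM (2.02, SE 0.64, adjusted p = 0.128) and Il4 at 45.5 against 12.3 CPM (1.88, SE 0.75, adjusted p = 0.179). The T cell list had 12 of 14 above 0 (0.25, adjusted p = 0.388) and the stroma list 5 of 7 (0.35, adjusted p = 0.365). MHC class I had 6 of 7 members below 0 (−0.06, adjusted p = 0.321) and the type I interferon list 8 of 10 (−0.12, adjusted p = 0.365). Macrophages (−0.05, adjusted p = 0.963), dendritic cells (−0.15, adjusted p = 0.819), neutrophils (0.22, adjusted p = 0.619) and neutrophil chemoattractants (0.21, adjusted p = 0.740) did not pass, and the other lists had an adjusted p of at least 0.107.

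In the MC-38 tumours 9 of 714 genes passed (5 higher, 4 lower), with 6 higher and 3 lower by library totals, 0 higher and 3 lower with housekeeping scaling and 0 higher and 4 lower with reference gene scaling, while DESeq2 called 50 (26 higher, 24 lower). The count was 3 without sash replicate 5 or wild-type replicate 3, 4 without sash replicate 2 or 6 or wild-type replicate 1, 5 without wild-type replicate 4 and 17 without sash replicate 4, and the class II list was lost without sash replicates 2, 4 or 5 or wild-type replicates 1, 3 or 5 (0.0657 to 0.114). With Col3a1 as a covariate 151 genes passed (78 higher, 73 lower), all 9 among them; Col3a1 itself stood at 7481 to 29569 CPM in sash and 13088 to 21596 CPM in wild-type tumours. Housekeeping scaling ended the class II call (0.522), as did reference gene scaling (0.406) and library totals (0.0510), and over the settings of this test its adjusted p ran from 0.0140 to 0.522.

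Tumours and preneoplastic lesions were compared within each genotype. Stage, age, the number of AOM injections and any difference between runs vary together here, and the comparison describes their sum. In wild-type mice Spp1, the osteopontin gene, rose from 7.04 ± 4.47 CPM (n = 3) to 1125 ± 688 CPM (n = 5; 7.34, SE 0.95, adjusted p = 6.10e-05), and Arg1, arginase 1 of myeloid cells, from 26.0 ± 1.34 to 2213 ± 1749 CPM (6.39, SE 0.71, adjusted p = 1.83e-05). Trat1 fell from 332 ± 169 to 2.83 ± 1.82 CPM (−6.87, SE 0.75, adjusted p = 1.83e-05) and B2m fell by 1.93 (SE 0.22, adjusted p = 2.06e-05). Cxcr2 had 387 counts in tumours and 1 in lesions, a ratio of 212 (95% interval 37.8 to 8380), and of 113 (20.2 to 4482) without wild-type lesion 3. Without lesion 1, which held that count, Cxcr2 was at least 52.9-fold higher.

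Further rises in wild type were Cxcl2 (7.13, SE 0.95), Cxcl5 (6.60, SE 0.73), the macrophage elastase gene Mmp12 (6.12, SE 0.90) and Cxcl3 (5.89, SE 0.99). Further falls were Tmigd1 (−4.77, SE 0.71), the antiviral synthetase genes Oas1g (−4.12, SE 0.62), Oas2 (−3.72, SE 0.59) and Oas1b (−3.58, SE 0.59), the B cell genes Pax5 (−3.52, SE 1.22) and Ms4a1 (−3.45, SE 1.10), and the interferon-induced GTPase gene Gbp2b (−3.11, SE 0.84). Their adjusted p lay between 1.83e-05 and 0.0346, and in all but Pax5 (4 of 5) 5 of 5 tumours lay beyond every lesion. Near-identical Oas1 and Gbp copies can share reads, so the values of single copies are uncertain. Kit differed by −0.94 (SE 0.41, adjusted p = 0.0856).

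In wild type 14 of 22 lists passed. Upwards moved neutrophils (5 of 5 higher, median 3.82, adjusted p = 0.00179), neutrophil chemoattractants (8 of 9 higher, 3.59, 0.00404), and inflammatory cytokines (6 higher and 1 lower of 12, 0.91, 0.00744). So did macrophages and monocytes (6 higher and 1 lower of 15, 1.00, 0.0256), the Th17 list (4 higher and 1 lower of 10, 0.30, 0.0263), endothelium (2 of 10 higher, 0.45, 0.0263) and the Th2 list (2 higher and 1 lower of 4, 0.89, 0.0481). Downwards moved the type I interferon list (7 of 10 lower, −1.26, 0.00179), B and plasma cells (6 of 10 lower, −2.69, 0.00404), MHC class I (4 of 8 lower, −0.84, 0.00492), as did cytotoxic and NK cells (5 of 9 lower, −1.50, 0.00597), T cells (6 lower and 1 higher of 14, −1.40, 0.0109), lymphoid tissue (3 of 7 lower, −1.63, 0.0263) and MHC class II (3 of 7 lower, −1.15, 0.0263). With an estimated correlation none of the 14 passed (adjusted p = 0.521 to 0.576). Adjusted over the list alone, more members passed in some lists, as in T cells (9 lower, 1 higher), macrophages (8 higher, 1 lower) and MHC class II (5 lower). Housekeeping scaling kept 5 of the 14, neutrophils, chemoattractants, cytotoxic cells, B and plasma cells and the type I interferon list, at adjusted p between 0.0114 and 0.0191. The Th2 call was not stable in direction: its median was −1.07 without a low-count filter (0.952), −0.36 in the fit of all 25 libraries (0.430), −0.50 without lesion 1 (0.565) and −0.46 without lesion 3 (0.524).

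In sash mice genes of myeloid cells were again among the large rises. Cxcr2 had 1606 counts in tumours and 2 in lesions, a ratio of 313 (95% interval 86.5 to 2587), and of 199.8 (55.2 to 1651) without sash lesion 3. Without sash lesion 2, which held both counts, Cxcr2 was at least 133-fold higher. Spp1 rose by 9.20 (SE 1.05, adjusted p = 1.27e-05), Cxcl3 by 7.85 (SE 1.00, adjusted p = 3.59e-05), Arg1 by 7.47 (SE 0.75, adjusted p = 1.01e-05) and Cxcl2 by 6.90 (SE 0.79, adjusted p = 1.27e-05). Tmprss6, a liver serine protease gene, and Afp, the alpha-fetoprotein gene, had 0 counts in sash lesions and were at least 20.7-fold and 13.8-fold higher in sash tumours, from a floor of 3 counts over the group. Without sash lesion 2 or 3 these bounds were 13.2-fold for Tmprss6, and 8.78-fold and 8.79-fold for Afp. Car4 fell from 51594 ± 15551 CPM (n = 3) to 902 ± 563 CPM (n = 5; −5.83, SE 1.06, adjusted p = 0.000509), Trat1 by 5.18 (SE 0.68), Cd163 by 4.81 (SE 1.00), and the calretinin gene Calb2 by 4.73 (SE 0.91). Gbp2b fell by 4.34 (SE 1.00), the monoamine oxidase gene Maob by 4.10 (SE 0.64), the muscle gene Ldb3 by 4.10 (SE 0.93) and the ankyrin gene Ank1 by 3.87 (SE 0.77), at adjusted p values between 3.89e-05 and 0.00278. Kit differed by −0.78 (SE 0.43, adjusted p = 0.142), while Hdc rose by 4.20 (SE 0.49, adjusted p = 1.27e-05). In every gene that passed here 5 of 5 tumours lay beyond every lesion.

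In sash 13 of 22 lists passed. Upwards moved neutrophils (5 of 5 higher, median 4.24, adjusted p = 8.25e-05), the Th2 list (2 of 4 higher, 1.35, 0.000219), neutrophil chemoattractants (9 of 9 higher, 4.97, 0.000365), macrophages and monocytes (11 higher and 1 lower of 15, 1.35, 0.00228), the Th17 list (4 higher and 1 lower of 10, 0.10, 0.0110), inflammatory cytokines (6 higher and 3 lower of 12, 0.78, 0.0113), regulatory T cells (4 of 8 higher, 1.58, 0.0119) and endothelium (3 of 10 higher, 0.0102), whose median of −0.01 differed in sign from its test. Downwards moved cytotoxic and NK cells (7 of 9 lower, −2.30, 0.000365), MHC class I (5 of 8 lower, −1.08, 0.00235), the interferon-gamma response (5 of 11 lower, −1.61, 0.00745), MHC class II (5 of 7 lower, −1.56, 0.0102) and B and plasma cells (2 of 10 lower, −2.36, 0.0375). None of the 13 passed with an estimated correlation (adjusted p = 0.442 to 0.631). Adjusted over the list alone, 7 class I genes, 7 interferon-gamma genes and 1 B cell gene were lower. Housekeeping scaling kept 4, the neutrophil, chemoattractant, Th2 and cytotoxic lists, and turned the median of the Th17 list to −0.05, while the endothelium median was 0.14 by library totals and 0.13 with reference gene scaling.

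Between stages 314 of 848 genes passed in wild type (165 higher, 149 lower) and 403 in sash (203 higher, 200 lower). Library totals, which shifted the median of all genes by 0.22 in wild type and 0.18 in sash, gave 223 higher and 90 lower, and 254 higher and 150 lower. Reference gene scaling in sash shifted the median by 0.16 and gave 237 higher and 148 lower, and housekeeping scaling called 132 genes in wild type and 235 in sash. Without wild-type lesion 1 the wild-type count was 183. Lists lost in wild type were most without lesion 1 (6 of 14 shared), lesion 3 (9) and lesion 2 (10), and 11 to 13 were shared without any 1 tumour. Reference gene scaling shared 11 of the 14, library totals and no low-count filter 12 each and the fit of all 25 libraries 13, and in sash library totals and reference gene scaling shared 12 of 13. In sash 10, 11 and 11 of 13 were shared without lesions 3, 1 and 2, and 11 to 13 without any 1 tumour.

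Whether the genotype effect itself differed between tumours and lesions was tested as a difference of effects. Lgals9 had the smallest adjusted p, with 4093 ± 1047 CPM in sash against 3612 ± 694 CPM in wild-type tumours and 2730 ± 351 against 7004 ± 1308 CPM in lesions (difference of log2 effects 1.56, SE 0.31, adjusted p = 0.0611). Fgf18 (−3.26, SE 0.66, adjusted p = 0.0611), H2-T24 (2.72, SE 0.59, adjusted p = 0.0641) and Gpc4 (−1.31, SE 0.28, adjusted p = 0.0641) followed. The interferon-induced genes Oas2 (3.14, SE 0.86) and Bst2 (1.86, SE 0.50) had adjusted p = 0.164, as had Erbb2 (−1.22). Kit had −1.62 in tumours and −1.78 in lesions, a difference of 0.16 (SE 0.61, adjusted p = 0.919). No list passed. The chemoattractant list had a median of 0.89 (adjusted p = 0.665) and the type I interferon list of 0.80 (3 higher adjusted over the list alone, adjusted p = 0.494). The smallest adjusted p of 22 lists was 0.159 for the Th2 list.

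By edgeR 0 of 848 genes passed this test, 128 had an unadjusted p below 0.05 and DESeq2 called 20 (8 higher, 12 lower), while the fit of all 25 libraries called 4. Without wild-type tumours 2 or 5 the count was 1 and 10, and without wild-type lesion 3 it was 3, and 1 list passed without wild-type tumour 2 and 1 without wild-type tumour 5. Reference gene scaling shifted the median of all genes by 0.20.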

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

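Tests chosen after seeing the data were scaling for the patterns below (except housekeeping list calls), Car4 and tumours without wild-type replicates 2 and 4. For interferon they were the wild-type cohort, the run term and replicates 1 and 2 alone. For class II they were Col3a1 and macrophage and dendritic cell genes. Of 98 values tested for a library apart from the rest of its group, 9 had such a library, and chance alone gives about 1 in 20. In wild-type tumours replicate 4 lay below the others, with a gap relative to the range of 0.847 for Cxcl2, 0.770 for Cxcr2, 0.856 for Fpr1, 0.746 for the neutrophil list, 0.844 for the chemoattractant list and 0.760 for the inflammatory cytokine list. Replicate 3 of the same group lay above the others for Hells (0.833). In sash MC-38 tumours Tpsab1 had counts in replicate 6 alone and Tpsb2 in replicate 5 alone, each with a gap of 1.

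Neutrophil and chemoattractant genes were higher in sash than in wild-type AOM tumours, with a median log2 difference of 2.12 over 13 genes. Each SE beside a median in this section is of another estimate, the group difference in the mean log2 level of the listed genes. It is not the error of the median, so readings that use it are approximate. Normal mucosa in the wild-type libraries, measured by Car4, would lower such genes there, but the median was 1.65 (SE 0.48) with Car4 as a covariate and 2.08 without wild-type replicates 2 and 4, which argues against it as the whole cause (bound 1.06), narrowly with Car4, where the neutrophil and chemoattractant calls ended (adjusted p = 0.114, and 0.0361 without the replicates). Scaling left 2.06 (SE 0.65) with reference genes and 2.15 (SE 0.67) with housekeeping genes, against an SE of 0.60 before, and both ended the list calls (adjusted p = 0.1003 and 0.0651). Of 100 splits of these libraries 3 gave as many genes at unadjusted p below 0.05 as the real 159, with 163 as the highest other, but by adjusted p the real split called 0 genes and the highest other 10, so chance was not excluded for single genes. The genotype named by the design stays open as an untested explanation, as do differences in ulceration or tumour size.

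Type I interferon genes were lower in sash than in wild-type lesions, with a median of −1.48 over 10 genes. Each inferred run held both genotypes equally, so the run term was no test of it (median −1.45, SE 0.08). The median was −1.63 within replicates 1 and 2 and −1.18 for replicate 3, with 9 of 10 genes lower. Housekeeping scaling left −1.33 while the SE went from 0.23 to 0.36, and it ended the list call (adjusted p = 0.108, against 0.0353 with reference genes), so the median argues against scaling as the whole cause and the call depends on it. A raised level in this wild-type cohort, as from an infection, remains open. The sash lesions stood 0.24 (SE 0.18) from the wild-type AOM-only group, and the wild-type lesions 1.18 above it. Low levels of these genes thus occurred in wild-type mice too. The data hold no sash mice of the other cohort, so mast cell loss cannot be told apart from a cohort difference.

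MHC class II genes were higher in sash than in wild-type MC-38 tumours, with a median of 0.67 over 5 genes. More macrophages and dendritic cells would raise their other genes, but the median of 24 such genes was −0.066, with 10 above 0. Their SD of 0.73 is no error of the median, and Cd163 (3.13) and Clec10a (1.98) had higher means. Stroma content, measured by Col3a1, left 0.68 (SE 0.13) as a covariate. Scaling left 0.60 (SE 0.21) with housekeeping genes and 0.76 (SE 0.23) with reference genes, against an SE of 0.12 before, and both ended the list call (adjusted p = 0.522 and 0.406). More such cells and the untested genotype of the design stay open.

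For the MC-38 tumours 4 of 100 splits called as many genes as the real 9, and the highest other called 144, which points to a structure of these libraries beside genotype. For wild-type stage 1 of 56 splits, the real one, called 314 genes, and the highest other, with wild-type tumours 2 and 4 placed among the lesions, called 247, which also points to structure. For sash stage 1 of 56 splits called 403, against 3 for the highest other, so chance was excluded. For the difference of genotype effects 2 of 100 splits gave 128 genes or more at unadjusted p below 0.05, with 147 as the highest other, but by adjusted p the real split called 0 and the highest other 5, so chance was not excluded for single genes. The 10 splits of 3 against 3 libraries were too few for a share below 0.05. In lesions 1 of them gave 22 genes and the highest other 0, also among the 4 splits that part all inferred pairs. With cromolyn during AOM the values were 2 and 0, after AOM 37 and 0, and between the wild-type experiments 119 and 0, each for 1 split of 10, while 4 of 10 splits of the cromolyn schedules gave 64 or more genes at unadjusted p below 0.05, with 156 as the highest other (by adjusted p 0 and 14).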

How the results depend on the processing

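The settings added after the data were seen were reference gene scaling, run as a term, replicates 1 and 2 alone, AOM only as control, wild-type tumours 2 and 4 left out, the Car4 and Col3a1 covariates, the list alternatives beyond the estimated correlation and housekeeping scaling, the block for the correlation, and single libraries left out of pooled counts. Where a value changed, the cause was not tested. Of 5020 gene values under alternatives 4242 kept direction and side of the threshold, 524 lost a call, 237 gained 1 and 17 turned sign, and of 624 list values these numbers were 403, 207, 1 and 13. Of the named genes called, 0 of 17 in lesions, 0 of 24 with cromolyn after AOM, 0 of 2 with cromolyn during AOM, 3 of 9 in MC-38 tumours, 5 of 20 between cohorts, 31 of 55 in wild-type stage and 43 of 54 in sash stage kept the call in every setting.

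DESeq2 called 82 genes in tumours, 70 in lesions, 39 with cromolyn during AOM, 6 between schedules, 50 in MC-38 tumours and 20 for the difference of genotype effects. Housekeeping scaling called 1 with cromolyn during AOM, 6 after AOM, 4 between schedules, 3 in MC-38 tumours, 132 in wild-type stage and 235 in sash stage. Library totals called 2 in tumours, 18 with cromolyn during AOM and 3 between schedules, and without a low-count filter 36 were called in lesions. Reference gene scaling called 41 in lesions and 4 in MC-38 tumours. A fit of all 25 libraries called 88 in tumours, 4 for the difference of effects and 0 for cromolyn during or after AOM by edgeR, with 43 and 69 at an unadjusted p below 0.05 (127 and 168 in the separate fits, where DESeq2 called 39 and 50). Tumours gave 6 without wild-type replicates 2 and 4. Lesions gave 66 with run as a term and 190 against AOM only, and MC-38 tumours 151 with Col3a1. Gene lists called fell from 40 to 1 with an estimated correlation, 13 with housekeeping and 25 with reference gene scaling.

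The replicate block gave 84 genes in lesions, where the numbers were taken from the data to pair the libraries. It gave 7 with cromolyn during AOM, 21 after AOM, 3 in MC-38 tumours and 24 lists. The block also ended the mast cell (adjusted p = 0.220) and class II (0.520) list calls in MC-38 tumours and all 3 list calls in AOM tumours. Outside the lesions the numbers did not pair libraries, with lowest correlations of −0.35 in tumours, −0.39 between schedules and 0.005 in MC-38 tumours. In the lesions the block changed the list calls and the gene count given beside them. Leaving out 1 library gave 0 to 17 genes in tumours, 0 to 68 in lesions, 0 to 15 with cromolyn during AOM, 1 to 8 after AOM, 0 to 1 between schedules, 3 to 17 in MC-38 tumours, 183 to 367 in wild-type stage, 0 to 10 for the difference of effects and 11 to 268 between cohorts. It moved the correlation with the sash effect from −0.52 to −0.30 for cromolyn during AOM and from −0.59 to −0.29 after it, while the block left −0.46 and −0.50.

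Values that turned sign were, against AOM only in lesions, Edn1 −0.11, Oas2 0.89, Oas3 0.68, Emp1 0.61, H2-T24 0.051, Irf7 0.47, Hpgds −0.11 and the interferon list 0.24. Hpgds was −0.086 with reference genes and −0.047 to 0.44 with 1 library left out, and Cma1 −0.89 to 0.046. Kit with cromolyn during AOM was −0.041 with housekeeping scaling and −0.091 to 0.44 with 1 library left out. Its difference of effects was −0.061 to 0.57, and between cohorts it was −0.20 with housekeeping scaling. The Th2 list in wild-type stage was −1.07 without a filter, −0.36 in the fit of 25 libraries and −0.50 to 1.09 with 1 library left out. In sash stage the Th17 list was −0.053 with housekeeping scaling, and the endothelium list 0.14 by totals, 0.11 with the block, 0.13 with reference genes and −0.15 to 0.36 with 1 library left out. Depth limits genes of few counts such as Cpa3 in lesions and Kit in MC-38 tumours.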

Other observations

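The genes below were chosen after their values were seen, and the pairing of sash and cromolyn effects was a planned test. Single genes not named above also differed between tumours and lesions. Ceacam1, an adhesion gene of mature colon epithelium, fell by 1.45 in wild type (SE 0.24, adjusted p = 0.000419) and by 1.46 in sash (SE 0.24, adjusted p = 0.000216). Cd44, a receptor for hyaluronan, rose by 1.53 (SE 0.38, adjusted p = 0.00722) and 2.39 (SE 0.40, adjusted p = 0.000276), and Il33, an alarmin of epithelium and stroma, by 2.74 (SE 0.48, adjusted p = 0.000645) and 4.61 (SE 0.53, adjusted p = 1.27e-05). Irf1, an interferon regulatory factor, fell by 1.13 (SE 0.18, adjusted p = 0.000405) and 1.80 (SE 0.18, adjusted p = 1.01e-05). In each of these genes 5 of 5 tumours lay beyond every lesion of their genotype.

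The effects of the sash mutation in lesions and of cromolyn would be alike in sign if both reported the loss of mast cell function. The correlation across genes was negative, −0.47 with AOM and −0.50 after it. Of 100 splits 14 and 20 gave as large a value (highest others 0.605 and 0.681), so chance was not excluded.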
